A study of Mus musculus with 10 samples.

How the data were processed

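The data are 10 RNA-seq libraries from mouse whole striatum of the Drd2-TRAP line CP101, in which ribosomes of D2 receptor cells carry EGFP. Per the labels' protocols, tagged polysomes were captured with anti-EGFP antibodies on Protein L magnetic beads and the RNA was purified with the Agilent Nanoprep kit. Each deposited file holds raw read counts per gene symbol from the authors, with 1 file per library. Per the submitters' processing notes, reads were processed with STAR 2.0.0e and HTSeq (version not given in the sources used here) on build mm10. The gene annotation and the strand setting of the counting are not given in the sources used here. Genes that overlap another gene, or that have near-identical copies, are therefore uncertain, since HTSeq in its usual setting drops reads that fit several places. This bears on ribosomal protein genes such as Rpl10a, Rps15 and Rps28, and Rpl10a reads can also come from the transgene. Of 141 named genes, 40 overlap another coding, long noncoding or antisense gene model in GENCODE. Groups and replicate numbers come from the sample titles and lanes from the sample descriptions.

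Each file lists 32531 gene symbols and the special counters of HTSeq, which name no gene and stay out of library sizes and tests. As a share of gene, no-feature and ambiguous reads, those in no annotated feature came to 12.9% to 14.4% in the IP libraries. They came to 25.5% in the input and 27.4% in the unbound library. Reads placed at several sites were set against a larger base, gene reads plus all special counters. Their share came to 33.3% to 47.1% in the IP libraries, 31.1% in the input and 25.9% in the unbound library. An entry named unknown held no reads and was dropped. The ribosomal RNA gene Rn45s took 4.67% to 7.30% of gene reads in the IP libraries other than cocaine IP 5, which had 1.5%. Gene reads per IP library ranged from 22975667 to 31631137, so that 3 reads, the floor used here, equal 0.095 to 0.131 CPM.

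Cocaine against saline was tested on the 8 IP libraries with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test (two-sided) with TMM scaling, genes kept by filterByExpr, treatment as the only term and Benjamini-Hochberg adjustment. The common biological coefficient of variation was 0.199. Lane 4 was set against lane 6 among the cocaine libraries in the same way. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with at least 3 measured members per list and adjustment over the lists. Camera with an estimated correlation and fry called 0 lists each. Of 35 lists, 33 could be tested. Symbols of the mitochondrially encoded genes are absent from the deposited counts, and fewer than 3 erythrocyte genes passed the low-count filter. IP libraries were compared with the single input or unbound library as log2 ratios of TMM-scaled CPM plus 1, for genes with a mean of at least 1 CPM. A gene counts as higher or lower when every IP library passed 2-fold, and list medians were set against 10000 random lists matched on mean expression. Positions are from GENCODE on GRCm38, the same assembly as mm10, and 683 of 685 symbols looked up had one.

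The tests, the gene lists and the rule for named genes were fixed before the data were examined. The rule names, for cocaine against saline, the genes past the threshold with the largest changes, filled up to 5 per direction with the smallest p among genes with a mean of at least 5 CPM. It adds up to 4 members per list described (those past the threshold, otherwise the 2 with the smallest p) and 11 fixed genes from Drd2 to Rpl10a. For the IP ratios it names the 10 highest and 10 lowest genes by the IP library closest to no change, and up to 4 members per cell type list. Gene models without a symbol, predicted genes and ribosomal copies were skipped: 1 among the lower genes for cocaine against saline, 16 among the lowest against input and 13 among the lowest against unbound RNA.

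The saline and cocaine IP groups share the numbers 1, 2 and 4. Deviations from the group means of libraries with the same number correlated at 0.706, 0.619 and 0.314 over the 9618 genes with a mean of at least 5 CPM, and each of these libraries correlated best with the library of its own number among those of the other treatment. Over all 13800 genes the values were 0.500, 0.337 and 0.0987, the last just under 0.1. The numbers were taken to pair the samples from these correlations, since the labels do not say what a number marks.

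The steps were tested on simulated counts with 200 changed genes. For cocaine against saline (13605 genes), 29.9% of genes changed 1.5-fold, 86.6% of those changed 2-fold and 100.0% of those changed 3-fold were recovered, with 7 unchanged genes called. For lane 4 against lane 6 (13537 genes) the shares were 17.9%, 79.1% and 98.5%, with 10 unchanged genes called. A shift of 0.4 given to 1 list (13612 genes) was fitted as 0.38 (camera adjusted p = 9.21e-15), and 0 other lists passed. For the IP ratios (12867 genes), 151 of 200 genes changed 3-fold were recovered, with 4 unchanged genes counted. All simulated counts were drawn independently per gene, without correlation between genes or structure shared by libraries. These figures therefore do not measure false calls or recovery where such structure exists, as among the real IP libraries.

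Alternatives covered RLE, upper-quartile and library-size scaling, a looser and a stricter low-count filter, DESeq2 1.42.0 and limma-voom with quality weights. As a covariate they used lane, glial and vascular marker level (the glial covariate) or 1 surrogate variable (sva 3.50.0). Others used the replicate number as a block or left out lanes or single libraries. For the ratios they covered scaling, prior, filter, fold limit and single libraries.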

Results

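Ribosome-bound RNA was profiled in adult mice of the Drd2-TRAP line CP101, which carries ribosomal protein L10a fused to EGFP in cells that use the dopamine D2 receptor gene. In the striatum these are mainly the medium spiny neurons (MSNs) of the indirect pathway. Mice had self-administered intravenous cocaine or saline in short sessions, and tagged polysomes were pulled down from the whole striatum with antibodies to EGFP. The question set by the design is which transcripts of these neurons differ after cocaine intake. The series holds 3 immunopurified (IP) libraries after saline (numbers 1, 2 and 4), 5 IP libraries after cocaine (numbers 1 to 5), 1 input library after saline and 1 unbound library after cocaine. Reads counted to genes came to 31234994, 29363097 and 27383303 in saline IP 1, 2 and 4. They came to 31581237, 27889286, 31631137, 25610349 and 22975667 in cocaine IP 1 to 5, to 18408782 in the input and to 20882691 in the unbound library. Libraries of a group differed from each other by far more than sampling noise (lowest chi-square per degree of freedom 23.3), so none was a copy of another. The labels do not say whether libraries came from separate animals, so p-values measure only the spread between these samples.

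The IP RNA carried the marks of indirect-pathway MSNs. All 10 fixed indirect-pathway markers were at least 2-fold higher in every IP library than in the reference library of the same treatment, with a median log2 ratio of 2.21 ± 0.13 (SD, n = 3) against saline input and 2.23 ± 0.23 (SD, n = 5) against cocaine unbound RNA. Drd2 itself (chromosome 9, 49340627 to 49408177) stood at 2476 ± 224 CPM (SD, n = 3) in saline IP and 357 CPM in the input, a mean log2 ratio of 2.79, and its ratio to unbound RNA was 2.51 ± 0.27 (SD, n = 5). Adora2a, an adenosine receptor gene (chromosome 10, 75316877 to 75334784), had ratios of 2.86 ± 0.34 (SD, n = 3) and 3.13 ± 0.27 (SD, n = 5). Penk, which encodes the enkephalin precursor (chromosome 4, 4133531 to 4138819), had ratios of 2.74 ± 0.44 (SD, n = 3) and 3.45 ± 0.51 (SD, n = 5). The orphan receptor gene Gpr6 had ratios of 2.44 ± 0.44 (SD, n = 3) and 3.44 ± 0.47 (SD, n = 5). Genes that all MSNs share were higher by less: the 13 pan-MSN markers had medians of 0.94 and 1.09, and 4 and 5 of them were at least 2-fold higher in every IP library, with Ptpn5 at 1.32 ± 0.25 (SD, n = 3) against input.

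Direct-pathway MSN markers were depleted, with medians of -2.56 ± 0.35 (SD, n = 3) against input and -2.34 ± 0.23 (SD, n = 5) against unbound RNA. Of these 10 genes, 9 and 8 were at least 2-fold lower in every IP library. Drd1, the dopamine D1 receptor gene (chromosome 13, 54051183 to 54055705), had 39.6 ± 6.27 CPM (SD, n = 3) in saline IP and 385 CPM in the input, and its ratios were -3.26 ± 0.23 (SD, n = 3) and -2.70 ± 0.32 (SD, n = 5). Pdyn, the prodynorphin gene, had ratios of -3.55 ± 0.87 (SD, n = 3) and -2.94 ± 0.47 (SD, n = 5), and the transcription factor gene Ebf1 had -3.48 ± 0.78 (SD, n = 3) and -3.54 ± 0.34 (SD, n = 5).

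Oligodendrocyte and astrocyte transcripts lay lower still. All 10 oligodendrocyte markers were at least 2-fold lower in every IP library of both treatments, with medians of -4.09 and -4.10, and so were all 10 astrocyte markers, with medians of -3.53 and -3.27. The astrocyte glutamate transporter gene Slc1a2 stood at -4.14 ± 0.92 (SD, n = 3) and -3.86 ± 0.30 (SD, n = 5). Oligodendrocyte precursor markers had medians of -2.77 and -2.69, microglia markers -2.31 and -2.01, and ependymal and choroid plexus markers -1.47 and -2.17. Endothelial and mural markers had a median of -1.95 against input and too few measured members against unbound RNA. GABA interneuron markers were also low (medians -2.19 and -2.82; 9 of 10 and 6 of 8 at least 2-fold lower), with the peptide genes Sst at -4.22 ± 0.54 (SD, n = 3) and Npy at -4.07 ± 0.35 (SD, n = 3) against input. Markers of pallial glutamatergic neurons had medians of -3.40 and -3.22, with all 5 and all 6 measured members lower. Medians of lists with scarce transcripts depend on the prior and the filter: against input that of GABA interneuron markers was -1.26 with a prior of 5 CPM, -3.64 with a prior of 0.1 CPM and -4.03 for genes with a mean of at least 5 CPM, and that of endothelial and mural markers -0.81 and -3.32 with these priors, so such lists cannot be ranked by depletion. Cholinergic interneurons, which express Drd2 themselves, kept closer to the reference: their 7 measured markers had medians of -0.73 and -0.30, and 0 of 7 passed the 2-fold limit. Midbrain dopamine neuron markers had medians of -1.27 and -1.06. Of the matched random lists, 14.5% lay below the endothelial median against input. Against input and unbound RNA the shares were 16.3% and 5.6% for ependymal markers and 7.28% and 8.15% for midbrain dopamine markers. They were 7.97% and 26.4% for cholinergic markers and 0% for astrocyte and oligodendrocyte markers. Depletion beyond that of similarly expressed genes is therefore not clear for the endothelial, ependymal, midbrain dopamine and cholinergic lists.

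**Figure D1:**
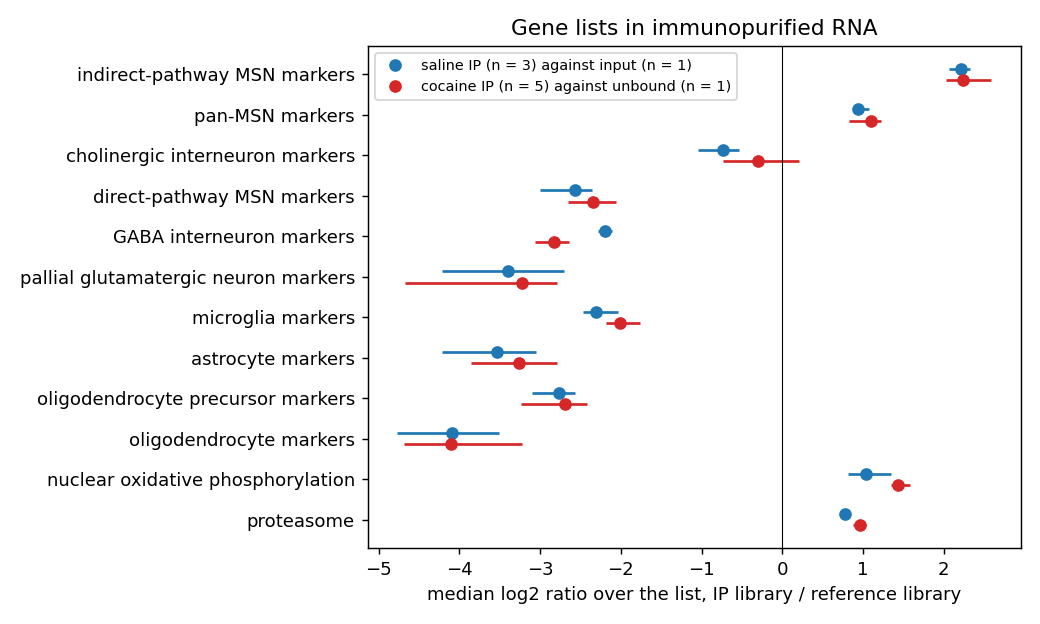
Median log2 ratio of 12 gene lists in each kind of IP library over its reference library. Points are medians over each list's genes of the mean ratio, and lines run from the lowest to the highest IP library. Indirect-pathway MSN markers lie at 2.21 and 2.23 and oligodendrocyte markers at -4.09 and -4.10.

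Among the genes ranked by the rule, with the skipped ones left out, the long noncoding RNAs Malat1 and Meg3 lay lowest in both comparisons. Malat1 (chromosome 19, 5795690 to 5802672) had a mean log2 ratio of -6.02 ± 0.57 (SD, n = 3) against input and -6.67 ± 0.56 (SD, n = 5) against unbound RNA, and Meg3 had -5.49 ± 0.24 (SD, n = 3) and -5.58 ± 0.53 (SD, n = 5). Snhg11 and Miat were among the 10 lowest against input and Snhg11 and Kcnq1ot1 among the 10 lowest against unbound RNA, beside the glial genes Fam107a, Gjc3 and Tmem88b. Sepp1, Npy and Gng11 completed the lowest 10 against input, and S100b and Mobp were among those against unbound RNA. The highest 10 against input were Ttc12, Drd2, Adora2a, Hpca, Penk, Irf4, Upb1, Gpr6, Sp9 and Tpm2. Against unbound RNA they were Adora2a, Gpr6, Ttc12, Penk, Drd2, Nts, Upb1, Churc1, Ndufa7 and Serpina9. Ttc12, a neighbour of Drd2 on chromosome 9 (49436963 to 49486225), had 2.89 ± 0.22 (SD, n = 3) and 2.79 ± 0.14 (SD, n = 5). Gene models of Meg3, Miat, Kcnq1ot1, Hpca, Upb1, Sp9 and S100b overlap a gene on the other strand. Their counts are therefore uncertain where the counting did not use strand. That of Churc1 overlaps a gene on the same strand, so its counts are uncertain in either case.

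Oxidative phosphorylation, proteasome and glycolysis lists had positive medians in the IP, but only the first had members at least 2-fold higher against input. The 59 nuclear oxidative phosphorylation genes had medians of 1.03 ± 0.27 (SD, n = 3) and 1.44 ± 0.10 (SD, n = 5), above all 10000 random lists matched on expression in both comparisons, and 12 and 42 of them were at least 2-fold higher in every IP library. The 30 proteasome genes had medians of 0.78 and 0.97, with 0 and 11 past the limit, and the 15 glycolysis genes 0.61 and 0.78, with 0 past it. The median over all genes was 0.13 and 0.17 with TMM scaling and -0.095 and -0.011 with library size alone, and none of the 3 lists changed sign under either.

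Across all genes, 211 of 12902 were at least 2-fold higher and 1495 at least 2-fold lower in all 3 saline IP libraries than in the input, or 70 higher and 1823 lower with library size alone as the scaling. Leaving out saline IP 1, 2 or 4 raised the first count to 377, 344 or 325. In all 5 cocaine IP libraries, 478 of 12643 genes were at least 2-fold higher and 1231 lower than in unbound RNA, or 247 higher and 1477 lower with library size alone as the scaling. Of 12554 genes compared in both, 128 were higher in both (7.96 for independent lists), 1058 were lower in both (124 for independent lists) and 0 went opposite ways. Mean ratios of the comparisons had a Pearson correlation of 0.927 and a Spearman correlation of 0.852 across genes, which are not independent replicates. The input and unbound libraries have no replicate, so no p-value is given, and a 95% Poisson interval on their counts covers counting error only (for Drd2 in the input, 348 to 365 CPM).

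Cocaine and saline IP libraries were close in the transcripts that mark these neurons. Drd2 had 1983 ± 362 CPM (SD, n = 5) after cocaine and 2369.9 ± 217 (SD, n = 3) after saline, a log2 fold change of -0.26 (SE 0.15), with CPM here scaled over the 8 IP libraries alone and above together with the input. Adora2a differed by -0.17 (SE 0.18), Penk by 0.21 (SE 0.26), Drd1 by 0.14 (SE 0.19), Pdyn by 0.19 (SE 0.39), the substance P precursor gene Tac1 by 0.20 (SE 0.22) and Rpl10a by -0.07 (SE 0.23). None of these passed the test, and the signs for Drd2, Adora2a, Penk and Drd1 were opposite with lane as a covariate. Of 13800 genes, 0 passed adjusted p 0.05 in edgeR's quasi-likelihood test (0 higher, 0 lower; smallest adjusted p = 0.9998). At unadjusted p under 0.05 there were 295 genes (152 higher, 143 lower) where 690 would be expected by chance. That expectation takes no account of structure shared by libraries. Over 56 splits of the 8 IP libraries into 3 and 5 the count had a median of 434.5, and the highest other split gave 2746. With the replicate number as a block (numbers 1, 2 and 4) there were 903, and with the number as a random effect 1103. The same 6 libraries without the block gave 141. Splits were not run with the block or the random effect, so whether 903 or 1103 exceeds chance was not tested. None of these fits had a gene past adjusted p 0.05 (smallest 0.0599). DESeq2 and limma-voom with quality weights also called 0 genes, with 443 and 429 at unadjusted p under 0.05. The groups did not overlap for 323 genes, 2.34% of those tested, where chance gives 3.57%. Among the 9618 genes with a mean of at least 5 CPM the median SE was 0.147, and for 98.6% of them the 95% interval lay within 1 log2 unit of 0.

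The genes with the smallest p, none past the threshold, lay on both sides. On the higher side, the cryptochrome gene Cry1 had 62.4 ± 8.39 CPM (SD, n = 5) after cocaine and 45.1 ± 4.25 (SD, n = 3) after saline, a log2 difference of 0.47 (SE 0.13). The adaptor subunit gene Ap1s3 differed by 0.56 (SE 0.15), Arid3a by 0.52 (SE 0.14), the anti-apoptotic gene Bcl2 by 0.52 (SE 0.15) and the splicing factor gene Tra2a by 0.44 (SE 0.13). On the lower side, the RNA-binding protein gene Raly differed by -0.75 (SE 0.22), the core splicing gene Snrpd3 by -0.62 (SE 0.20), the fatty acid transporter gene Slc27a1 by -0.57 (SE 0.18), the DNA repair gene Xrcc3 by -0.43 (SE 0.13) and the cochaperone gene Sgta by -0.35 (SE 0.12). Raly, Snrpd3, Xrcc3 and Bcl2 overlap other gene models, so reads of those genes can enter their counts.

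Immediate early genes, which neurons switch on within minutes of activity, were lower as a list after cocaine by the camera test (median log2 fold change -0.23 over 18 measured members, 14 of them negative; camera adjusted p = 0.00689 over 33 lists). The call was lost with an estimated correlation between members (adjusted p = 0.663 with an estimated correlation), and 0 members passed, also when adjusted over the list alone. Arc, a regulator of synaptic receptor traffic (chromosome 15, 74669083 to 74672570), had 23.1 ± 12 CPM (SD, n = 5) after cocaine and 38.2 ± 8.39 (SD, n = 3) after saline, a difference of -0.72 (SE 0.33). Junb differed by -0.47 (SE 0.20), Egr4 by -0.38 (SE 0.17), Fos by -0.73 (SE 0.69), Fosb by -0.17 (SE 0.20) and Egr1 by -0.12 (SE 0.19). Lane splits the cocaine group here. The list level, as mean log2 CPM, was 3.93 and 3.95 in the cocaine libraries of lane 6, 3.17 to 3.37 in those of lane 4 and 3.62 to 3.90 in the saline libraries. With lane as a covariate the list's median was 0.038 (camera adjusted p = 0.496), and without the 3 lane 4 libraries it was -0.018 (adjusted p = 0.668). With the replicate block it was -0.20 (adjusted p = 0.162), and in an unpaired fit of the same 6 libraries -0.19 (adjusted p = 0.369). The call also ended without saline IP 2 (-0.095, adjusted p = 0.187) or cocaine IP 5 (-0.15, adjusted p = 0.168), and without saline IP 1 the median was larger at -0.36 (adjusted p = 3.84e-04). Over 29 alternatives its adjusted p ran from 2.24e-07 to 0.994, with 17 under 0.05.

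**Figure D2:**
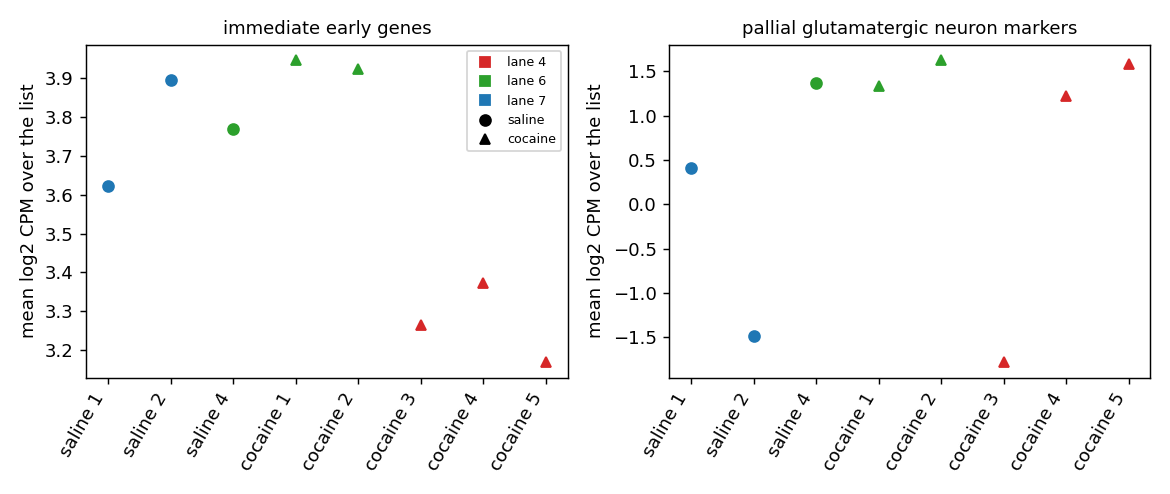
Mean log2 CPM of the immediate early genes and of the pallial glutamatergic neuron markers in each of the 8 IP libraries, with colour for sequencing lane and shape for treatment. For immediate early genes the 3 cocaine libraries of lane 4 lie at 3.17 to 3.37, below the saline range of 3.62 to 3.90. For pallial markers cocaine IP 3 lies at -1.78 and saline IP 2 at -1.48.

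Opioid and neuropeptide genes were higher as a list after cocaine (median 0.19 over 15 members, 13 positive; camera adjusted p = 0.0341, and adjusted p = 0.613 with an estimated correlation). Cartpt, the gene of the cocaine- and amphetamine-regulated transcript (chromosome 13, 99898489 to 99901091), had 3.21 ± 1.41 CPM (SD, n = 5) after cocaine and 1.44 ± 0.31 (SD, n = 3) after saline, a difference of 1.15 (SE 0.36), and the corticotropin-releasing hormone receptor gene Crhr1 differed by 0.48 (SE 0.33). Of the 15 members 0 passed, also when adjusted over the list alone. The call ended with lane as a covariate (median 0.17, adjusted p = 0.777), with the replicate block (0.091, adjusted p = 0.284) and in the unpaired fit of those 6 libraries (0.047, adjusted p = 0.369). It also ended without saline IP 1 (0.15, adjusted p = 0.109), saline IP 2 (0.23, 0.0820), cocaine IP 2 (0.16, 0.0798) or cocaine IP 5 (0.15, 0.168), where the median stayed between 0.15 and 0.23. Without the 3 lane 4 libraries the median was 0.10 (camera adjusted p = 0.399). Among cocaine libraries the list was higher in lane 4 than in lane 6 (median 0.33, 11 of 15 members positive), without passing (camera adjusted p = 0.108). Its adjusted p for treatment ran from 0.00120 to 0.836 over 29 alternatives, with 14 under 0.05.

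Ependymal and choroid plexus markers, from cells outside the neurons studied, were lower as a list (median -0.73 over 3 members, all 3 negative; camera adjusted p = 0.0383, and adjusted p = 0.613 with an estimated correlation). The transthyretin gene Ttr, abundant in choroid plexus, differed by -2.43 (SE 0.81) and alone passed when adjusted over the list alone (adjusted p = 0.0353). Ttr was lower after cocaine for all 3 shared numbers, at 4.27 and 0.72 CPM in saline and cocaine IP 1, 0.27 and 0.036 CPM in number 2 and 0.70 and 0.19 CPM in number 4. The 0.036 CPM of cocaine IP 2 lies below the floor of that library (0.108 CPM). Cocaine IP 3 and 5, without a saline partner, had 0.29 and 0.35 CPM, above saline IP 2. The list level, as mean log2 CPM, was also lower within all 3 numbers, from 1.54 to 0.46, from 0.23 to -0.94 and from 0.29 to -0.093. Such agreement was not particular to this list: microglia markers were also lower, and endothelial and neuropeptide lists higher, after cocaine within all 3 numbers. The ciliogenesis gene Foxj1 differed by -0.73 (SE 0.31). Among these fits the call ended with lane as a covariate (median -0.42, adjusted p = 0.777), with the replicate block (-0.71, adjusted p = 0.0757) and in the unpaired fit of the same 6 libraries (-0.70, adjusted p = 0.302). It also ended without saline IP 1 (-0.60, adjusted p = 0.318), cocaine IP 2 (-0.65, 0.109) or cocaine IP 5 (-0.66, 0.175), with medians near that of all 8 libraries, whereas without saline IP 4 the median was -1.15 (adjusted p = 0.00279) and without lane 7 it was -0.40 (adjusted p = 0.665). Its adjusted p ran from 0.00279 to 0.836 over 26 alternatives, with 14 under 0.05.

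The other 30 lists did not pass in the camera test of all 8 libraries with treatment as the only term. Among them 0 members passed the test over all genes or adjusted over the list alone. Pallial glutamatergic markers, of neurons that lie outside the striatum, had a median of 0.63 (camera adjusted p = 0.199, and adjusted p = 0.9746 with an estimated correlation), with Neurod2 at 1.25 (SE 0.76) and Neurod6 at 0.79 (SE 0.61). Their level varied widely between libraries of both groups, and they passed with the replicate block (median 1.14, adjusted p = 1.99e-06), in an unpaired fit of the same 6 libraries (1.0, adjusted p = 1.46e-09) and without cocaine IP 3 (0.92, adjusted p = 1.21e-09), the library with the lowest level. The median was 1.45 without saline IP 4 (adjusted p = 0.0532), 0.24 without saline IP 2, 0.074 without lane 7 and -0.0060 in limma-voom with quality weights. Over 28 alternatives their adjusted p ran from 1.21e-09 to 0.994, with 5 under 0.05. Endothelial and mural markers had a median of 0.73 (adjusted p = 0.0951, and adjusted p = 0.613 with an estimated correlation), with Pdgfrb at 1.41 (SE 0.52). Only 4 of 10 members were measured, and they were scarce, with a list level of -2.26 to -0.44 mean log2 CPM. They passed without cocaine IP 3 (0.96, adjusted p = 0.00260) and with the replicate number as a random effect (1.05, adjusted p = 0.0391). They also passed with the glial covariate (1.08, adjusted p = 0.0447) and with 1 surrogate variable (1.13, adjusted p = 0.0470). The glial covariate is a mean level that includes these same markers, so its fit is no separate support. The endothelial and mural markers did not pass with the block over pairs (0.69, adjusted p = 0.0903). Their median was 0.32 without saline IP 2 (adjusted p = 0.801), 0.34 without saline IP 4 (0.303), 0.44 without cocaine IP 5 (0.175) and 1.12 without saline IP 1 (0.171). Over 28 alternatives their adjusted p ran from 0.00260 to 0.836, with 4 under 0.05. Single libraries also moved glial lists. Oligodendrocyte markers stood at -0.24 (adjusted p = 0.337) and passed at -0.54 without saline IP 2 (adjusted p = 1.97e-04) and at -0.48 without cocaine IP 1 (adjusted p = 0.00582), with 3 of 29 alternatives under 0.05 (highest 0.994). Astrocyte markers stood at -0.017 (0.904) and passed in opposite directions, at 0.49 without saline IP 1 (adjusted p = 0.00831) and at -0.37 without saline IP 2 (adjusted p = 0.00877), the only 2 of 29 alternatives under 0.05 (highest 0.994). Microglia markers stood at -0.23 (0.196) and passed at -0.39 without saline IP 2 alone (adjusted p = 0.0252; highest of 28 alternatives 0.994), and oligodendrocyte precursor markers stood at -0.0077 (0.904). Neuronal markers had medians of -0.020 for indirect-pathway MSNs (adjusted p = 0.685), 0.16 for direct-pathway MSNs (0.442; 0.19 without saline IP 1, adjusted p = 0.0226, with 2 of 29 alternatives under 0.05 and the highest 1.0), 0.00027 for pan-MSN genes (0.904), 0.13 for cholinergic (0.904), 0.043 for GABA interneurons (0.938) and 0.14 for midbrain dopamine neurons (0.805).

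Synaptic and excitability lists had medians from -0.055 to 0.085. Dopamine and cAMP signalling had a median of 0.00050 (camera adjusted p = 0.904), with Creb1 at 0.25 (SE 0.12) and Crem at 0.22 (SE 0.11). Glutamate receptors and postsynaptic scaffold had 0.049 (0.307), with Homer2 at 0.41 (SE 0.15). GABA receptors and inhibitory synapse genes had 0.085 (0.322), potassium channels 0.080 (0.566), calcium and sodium channels 0.071 (0.694), synaptic vesicle genes 0.0088 (0.853), actin and spine genes -0.047 (0.426) and MAPK feedback genes -0.055 (0.963). The spine actin-binding gene Dbn1 stood at -0.35 (SE 0.12) and the MAPK inhibitor gene Spred1 at 0.23 (SE 0.11). Without cocaine IP 1, 4 of these lists passed as higher after cocaine: GABA receptors (0.17, adjusted p = 0.00120), calcium and sodium channels (0.20, 0.00120), potassium channels (0.16, 0.00779) and glutamate receptors (0.061, 0.00996). Over 29 alternatives GABA receptors were under 0.05 in 2 and the other 3 lists in 1 each, with highest adjusted p from 0.994 to 1.0.

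Metabolic and stress lists had medians from -0.11 to 0.11. Oxidative phosphorylation genes had a median of -0.037 (camera adjusted p = 0.768), with Atp5b at 0.23 (SE 0.10), and glycolysis 0.022 (0.853), ribosomal protein genes -0.046 (0.199), proteasome -0.024 (0.904), heat shock and unfolded protein response 0.11 (0.193) and cholesterol synthesis -0.0049 (0.968). Glucocorticoid-responsive genes had -0.11 (0.196), with Cdkn1a at -0.41 (SE 0.19), circadian clock genes 0.051 (0.307), with Ciart at -0.40 (SE 0.18), chromatin regulators 0.023 (0.768), with Hdac4 at 0.31 (SE 0.13) and Ehmt2 at -0.35 (SE 0.16), and interferon and inflammatory genes -0.060 (0.572), with Icam1 at -1.12 (SE 0.48). The sign of the median differed from that of the camera test for pan-MSN, midbrain dopamine, astrocyte, oligodendrocyte precursor, dopamine and cAMP, synaptic vesicle and cholesterol genes, and the mean and median of MAPK feedback genes differed in sign. Leaving out 1 library changed some of these calls. Oxidative phosphorylation passed at -0.16 without saline IP 1 (adjusted p = 1.07e-05) and at 0.098 without saline IP 2 (adjusted p = 3.52e-04), and ribosomal protein genes at -0.16 (adjusted p = 1.11e-07) and 0.079 (adjusted p = 0.0404). The heat shock list passed at 0.16 without cocaine IP 1 (adjusted p = 0.00120). These 3 lists were under 0.05 in 3, 4 and 2 of 29 alternatives, with highest adjusted p of 0.998, 0.994 and 0.994. Cholesterol synthesis passed with lane as a covariate (median -0.22, adjusted p = 0.00535), the only one of 29 alternatives where it did (highest adjusted p = 0.994). Saline IP 1 and 2 ran on lane 7, cocaine IP 3, 4 and 5 on lane 4, and both treatments met only on lane 6 (1 saline and 2 cocaine libraries), so a fit with lane rests on those 3 for treatment.

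Within the cocaine group, lane 4 (3 libraries) was set against lane 6 (2 libraries) to size the difference between lanes at 1 treatment. Immediate early genes had a median log2 difference of -0.51 (lane 4 minus lane 6), with 16 of 18 members negative (camera adjusted p = 7.87e-07, and adjusted p = 0.786 with an estimated correlation), and 4 members passed when adjusted over the list alone. Arc had 14.9 CPM in lane 4 and 35.3 CPM in lane 6, a log2 difference of -1.24 (SE 0.19), and Fos, the prototype immediate early gene (chromosome 12, 85473890 to 85477273), had 0.34 and 2.64 CPM, a difference of -2.92 (SE 0.41). Neither passed edgeR's test over all genes. Calcium and sodium channels were higher as a list in lane 4 (median 0.35, camera adjusted p = 7.15e-04, and adjusted p = 0.829 with an estimated correlation), and so were cholesterol synthesis genes (0.21, adjusted p = 0.00460, and adjusted p = 0.829 with an estimated correlation). Pallial markers differed by -0.52 (camera adjusted p = 0.00602, and adjusted p = 0.829 with an estimated correlation), and in cocaine IP 3 alone their level was -1.78 where the other 4 cocaine libraries lay at 1.22 to 1.63. For calcium and sodium channels the difference rests on cocaine IP 1 (mean log2 CPM 5.98), since cocaine IP 2, also of lane 6, lay at 6.49, inside the lane 4 range of 6.41 to 6.65. GABA receptors (6.37 and 6.88 in lane 6, 6.75 to 6.99 in lane 4) and glutamate receptors (6.64 and 6.90, 6.89 to 7.04) did likewise. Of 32 lists tested 10 passed in camera (7 higher, 3 lower in lane 4), among them GABA receptors (0.20, adjusted p = 0.00460), glutamate receptors (0.23, 0.00605) and oxidative phosphorylation (-0.11, 0.00460), and 0 passed with an estimated correlation (adjusted p = 0.829 for each of these 3). Among 13746 genes, 0 passed adjusted p 0.05 in edgeR, with 744 at unadjusted p under 0.05. DESeq2 called 5: Arc and Fos lower in lane 4, and Onecut2, BC071253 and Cdr1 higher, the last 3 named only after their values were seen. Without cocaine IP 2, which leaves cocaine IP 1 alone for lane 6, edgeR called 407 genes.

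The first principal component of the 8 IP libraries (31.9% of the variance) did not separate the treatments. Saline IP 1 (-40.0) and cocaine IP 1 (-38.6) lay at one end, saline IP 2 (34.2), cocaine IP 3 (20.0) and cocaine IP 2 (19.1) at the other, and saline IP 4, cocaine IP 4 and cocaine IP 5 lay between. The second component (18.3%) set cocaine IP 5 apart (42.4, where the others lay at -26.6 to 6.35).

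**Figure D3:**
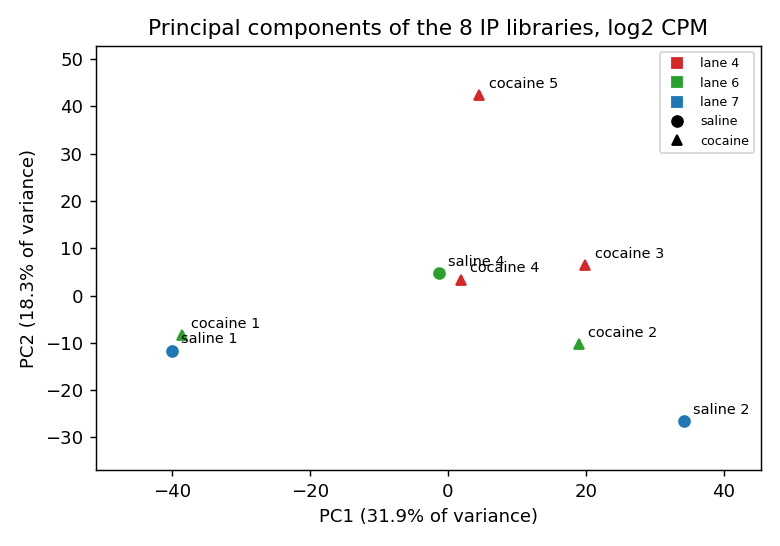
First and second principal components of log2 CPM in the 8 IP libraries, with the share of variance on each axis, colour for sequencing lane and shape for treatment. Both libraries numbered 1 lie near -40.0 and -38.6 on the first component, and cocaine IP 5 lies at 42.4 on the second.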

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

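The counts over other splits of the samples were planned, whereas the tests of treatment without lane 4, of pallial neurons, of a batch that follows lane, of lane behind the pairing, of RNA from other cell types and of an even carry-over were chosen only after the results they bear on were seen. Of 123 library values, gene levels and list levels tested in the 5 cocaine IP libraries, 14 had 1 library far from the other 4. Chance alone singles out about 1 in 20 groups (5%).

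The immediate early genes are the first pattern. Treatment that lowers the list in every cocaine library is argued against, since without the 3 lane 4 libraries its median was -0.018, and both lane 6 cocaine libraries (3.93 and 3.95) lay above all 3 saline libraries (highest 3.90). Fewer pallial neurons in lane 4 are argued against too, but only for cocaine IP 4 and 5. Their pallial level differed from that of cocaine IP 1 and 2 by only -0.078, while their immediate early level differed by -0.67. Cocaine IP 3, also of lane 4, was left out of this comparison, and its pallial level was -1.78. For that library the explanation stays open. A handling or sequencing batch that follows lane cannot be told apart from a difference between animals or sessions, because lane 4 (median -0.51 against lane 6) holds only cocaine libraries. The low level was seen in cocaine IP 3, 4 and 5, which share a lane, and the labels do not say when they were collected. A response to cocaine in those libraries alone stays open as well.

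The resemblance of libraries with the same replicate number is the second pattern. Lane is argued against, since no same-numbered pair shares a lane (lanes 7 and 6 for numbers 1 and 2, lanes 6 and 4 for number 4). The 2 saline libraries of lane 7 lie 2.40 times the median distance apart on the first principal component. They are numbers 1 and 2, which that component had already been seen to part, so this distance adds no separate support. More RNA of other cell types in the libraries numbered 1 than in those numbered 2 is a candidate explanation. The difference between them correlated across genes with depletion measured in the other 4 IP libraries (Spearman 0.47). Oligodendrocyte, astrocyte and microglia markers were higher in number 1 by 1.57, 1.42 and 1.03 log2 units while indirect-pathway MSN markers differed by -0.50. The pair numbered 4 was not compared in this way. Mean log2 CPM of glial and vascular markers was 2.21 and 2.13 in number 1, 0.90 and 0.92 in number 2 and 1.39 to 1.76 in the others. The contrast can come from more such RNA in number 1, less in number 2 or both. Whether this was one even carry-over of whole-striatum RNA stays open: the added share of the unbound level differed between 6 other-cell-type lists by 3.11 times in the saline pair and 3.23 times in the cocaine pair, but when the gene that most narrows the gap was left out of each list they differed by at least 2.17 times in the saline pair and only 1.15 times in the cocaine pair (cholinergic markers, of cells that express Drd2, and pallial markers, at 4.47% and -2.18% in the pairs, were not used). No biological explanation was tested for this pattern, because the labels do not say what a number marks.

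The counts for cocaine against saline are the third pattern. Chance cannot be excluded for the lists, since 48 of 56 splits of the 8 IP libraries into 3 and 5 gave at least the real 3 (highest other 16) and 19 of 56 called the immediate early genes. For genes the real count is 0, so all 56 splits had to reach it and the comparison says nothing (highest other 259). The splits with 259, 210 and 44 genes each kept saline IP 1 and cocaine IP 1 together, which points to a structure of the samples, and splits by lane gave as many lists (lane 4 against the rest 9, lane 6 against the rest 4; 0 genes in both). Of the 8 splits that part all 3 pairs, 6 gave as many lists (highest other 8), and the real split alone reached 295 genes at unadjusted p under 0.05, with 222 the highest of the other 7. Even the first rank among only 8 splits cannot exclude chance. Over all 56 splits, 40 had at least 295 such genes.

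Cocaine IP 3 lay lowest for the pallial list (-1.78, others 1.22 to 1.63), for its member Neurod6 (0.55 CPM, others 2.50 to 3.13), for the midbrain dopamine list (0.54, others 1.59 to 1.80) and for its member Nr4a2 (0.615 CPM, others 7.86 to 9.08), and highest for Spred1 (530.4 CPM, others 434 to 462). Cocaine IP 1 lay highest for the direct-pathway gene Isl1 (7.12 CPM, others 2.75 to 3.85), the interneuron gene Npy (3.06 CPM, others 1.25 to 1.57), the myelin gene Cnp (75.9 CPM, others 28.4 to 39.5) and the glucocorticoid-responsive list (4.55, others 4.23 to 4.32). Cocaine IP 2 lay highest for the ribosomal protein list (3.94, others 3.82 to 3.84) and lowest for the chromatin list (5.71, others 5.90 to 5.96). Cocaine IP 5 lay lowest for the share of Rn45s (1.5%, others 5.17% to 6.24%) and for the microglia gene Ctss (1.30 CPM, others 2.69 to 3.19), and cocaine IP 4 highest for the cholesterol synthesis gene Mvk (6.97 CPM, others 4.70 to 5.18).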

How the results depend on the processing

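The random-effect block, the fit without Rn45s, the fits without both libraries numbered 1 or 2 and the ratios without 5 abundant RNAs were chosen after seeing the data, and all other alternatives were planned. For cocaine against saline, all 27 alternatives gave 0 genes past adjusted p 0.05, with 107 to 1103 at unadjusted p under 0.05. Of 2240 values of the 84 named genes under them, 77 had the other sign and 0 passed.

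The replicate block over the 3 pairs gave 0 genes (903 at unadjusted p under 0.05, smallest adjusted p = 0.0599) and 1 list, and the unpaired fit of the same 6 libraries also gave 1 list, the pallial markers in both. The 3 list calls of the 8 libraries were already absent from that unpaired fit (adjusted p = 0.369, 0.369 and 0.302), and against it the block over pairs changed no call. As a random effect in limma-voom over all 8 libraries the block gave 0 genes and 4 lists: it ended the neuropeptide call (0.088, adjusted p = 0.121) and added pallial (1.22, adjusted p = 0.0294) and endothelial markers (1.05, adjusted p = 0.0391). That fit also changes the tool, and the cause was not tested.

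The 3 lists past the threshold became 1 without a filter, 1 with the stricter filter, 1 with lane as a covariate and 1 without lane 4, 5 with the glial covariate, 5 with 1 surrogate variable, 0 without lane 7, 6 without both libraries numbered 1, 1 without both numbered 2, 0 with an estimated correlation and 0 with fry. Leaving out single libraries gave 0 to 8 lists. The adjusted p of the immediate early genes ran from 2.24e-07 to 0.994 over 29 alternatives (17 under 0.05), that of the neuropeptide genes from 0.00120 to 0.836 (14 under 0.05) and that of the pallial markers from 1.21e-09 to 0.994 (5 of 28 under 0.05). The immediate early median turned to 0.038 with lane as a covariate (camera adjusted p = 0.496). Without lane 4 it was -0.018, where the set test leaned higher without passing (camera adjusted p = 0.668). Cholesterol synthesis moved from -0.0049 to -0.22 with lane as a covariate. Without saline IP 2, astrocyte markers moved from -0.017 to -0.37, oxidative phosphorylation from -0.037 to 0.098 and ribosomal proteins from -0.046 to 0.079. Without saline IP 1 these lists stood at 0.49, -0.16 and -0.16. Lane and fewer samples are the construction of these fits, and beyond that the cause was not tested. Of 948 list values, 877 kept their side of the threshold (165 of them with the other sign, all uncalled), 37 lost a call and 28 gained one (19 higher, 9 lower). In 6 more the set test changed direction, but none was called in both fits. Of these, the immediate early genes lost their call and the other lists gained one.

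Lane 4 against lane 6 gave 5 genes with DESeq2, and 0 to 407 in edgeR when single libraries were left out. The 211 genes higher in saline IP became 70 with library size alone, 125 with a prior of 5 CPM and 9 at 4-fold, and the 1495 lower became 781 with that prior, 660 at a mean of at least 5 CPM and 567 at 4-fold. The 478 genes higher in cocaine IP became 247 with library size alone, 294 with a prior of 5 and 8 at 4-fold, and the 1231 lower became 756 with that prior, 556 at a mean of at least 5 CPM, 1891 with any read and 490 at 4-fold. A stricter limit or filter counts fewer genes by construction; the cause of the other shifts was not tested. Without single libraries the counts ran from 325 to 377 and 1638 to 1804 for saline, and from 482 to 699 and 1318 to 1395 for cocaine. Of 327 and 381 list medians of these ratios, 63 and 59 moved beyond 1 SD, 9 and 3 changed sign, and 0 of those for lists with a median of at least 1 did.

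Depth limits genes near the floor of 3 reads (0.095 to 0.131 CPM in the IP libraries), such as Ttr and Pdgfrb.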

Other observations

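Genes next to Drd2 on chromosome 9, looked up only after Ttc12 had been seen among the highest genes, differed sharply in the IP. Ankk1 (49415194 to 49427021), which lies between Drd2 and Ttc12, had mean log2 ratios of 1.5 ± 0.19 (SD, n = 3) against input and 0.98 ± 0.16 (SD, n = 5) against unbound RNA. Ttc12 reached 469 CPM in saline IP and 61.8 CPM in the input. The flanking genes stood apart: Ncam1, on the far side of Ttc12 (49502136 to 49798925), had -0.97 ± 0.36 (SD, n = 3) and -0.37 ± 0.37 (SD, n = 5). On the other side of Drd2 the nearest compared gene, the scarce Gm4894 (1.17 CPM in saline IP), had -0.49 and -1.15. Beyond it Zw10 had -0.98 and -0.30 and Usp28 -0.24 and 0.019. The sources used here do not say how much of this region the transgene carries.

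Lists other than cell type markers and the 3 metabolic lists above had medians between -0.76 and 0.75 in the IP. Circadian clock genes had median log2 ratios of 0.66 and 0.43 against input and unbound RNA, dopamine and cAMP signalling genes 0.69 and 0.75, actin and spine genes 0.59 and 0.68 and MAPK feedback genes 0.63 and 0.63. Calcium and sodium channels had 0.28 and 0.54 (above 29.1% and 92.5% of matched random lists). The heat shock list had 0.32 and 0.69 (above 58.35% and 99.6% of them). Interferon and inflammatory genes (9 of 20 measured) had -0.76 and -0.70, above 11.6% and 13.6% of matched random lists. Depletion beyond that of similarly expressed genes is therefore not clear for them. Medians near 0 were those of glutamate receptors and scaffold (0.21 and 0.43), GABA receptors (0.20 and 0.25), synaptic vesicle genes (0.17 and 0.28), potassium channels (-0.0032 and 0.20), ribosomal proteins (0.069 and 0.44), glucocorticoid-responsive genes (0.18 and 0.31), cholesterol synthesis (-0.25 and 0.085), chromatin regulators (-0.037 and 0.12), neuropeptide genes (-0.32 and 0.17) and immediate early genes (0.35 and -0.31). Matched random lists did not centre on 0, with medians against input of 0.44 for synaptic vesicle and 0.33 for chromatin genes. Against input, few of them lay below chromatin (0.24%), potassium channel (1.15%), cholesterol (1.24%), synaptic vesicle (1.45%) and neuropeptide genes (1.91%). Against unbound RNA these shares were 5.84%, 21.5%, 23.4%, 18.85% and 48.8%. For ribosomal proteins they were 23.0% against input and 99.5% against unbound RNA. For circadian clock genes they were 99.3% and 65.55%, and for immediate early genes 94.7% and 3.04%. With library size alone the sign turned, against input, for glutamate receptors, GABA receptors, synaptic vesicle, ribosomal protein and glucocorticoid-responsive genes, and against unbound RNA for neuropeptide, cholesterol and chromatin genes.

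The hemoglobin gene Hbb-bs, the only erythrocyte marker measured, had ratios of -2.90 ± 0.06 (SD, n = 3) and -2.19 ± 0.23 (SD, n = 5). Prkcd, named only after its values were seen, had 16.4 CPM in cocaine IP 1 and 0.24 to 3.8 CPM in the other 7 IP libraries.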
